A study of Homo sapiens with 168 samples.

How the data were processed

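RNA and surface antibodies were measured in the same single blood mononuclear cells, in 84 RNA libraries paired with 84 antibody libraries. Per the labels' protocols, frozen cells were thawed, treated with DNase I, stained with 99 barcoded antibodies, pooled in groups of 16 samples and captured with the 10x 3′ v3 chemistry. Per the submitters' processing notes, Cell Ranger 3.1.0, Scanpy 1.4.6 and the GRCh38 build were used. The deposited matrices held raw whole-number counts of unique molecules per gene (33538 genes) or per antibody and cell, with no normalization. Each deposited cell had 500 to 16430 RNA counts (median 6079), 263 to 2500 detected genes (median 1817, with 27 cells at 2500) and at most 20% mitochondrial counts (median 9.14%), so cells outside these limits were not analysed here.

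The labels name the time point and the donor of each library. The title of 1 library carried a sample number that disagreed with its library name, its time point was taken from the time label, and no fit was made to test this choice. The 84 libraries belonged to 68 samples, of which 16 had 2 runs. The runs of a sample shared 4 cell barcodes in total over the 16 pairs. Their summed counts correlated across genes at an r of 0.785 to 0.982 (median 0.944). The sums differed by more than counting noise in 16 of 16 pairs (chi-square test), which sums over different cells would give in nearly any case. The runs were summed and counted as 1 sample because they shared the donor and the time point. Donor was the block in every fit, as the labels name the donor. In a check of the pairing, deviations from the time point means correlated at a median r of 0.191 between samples of the same donor and -0.041 between samples of other donors, and 58 of 97 same-donor pairs lay above 0.1.

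Per the labels' protocols, samples of different donors and times were mixed over the experiments. Cells with at least 200 genes and at most 20% mitochondrial counts were kept, which kept all 97817. Counts were normalized per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 2 gave the clusters (Scanpy 1.11.5, igraph 0.11.9, Python 3.11.15). Sex-linked genes (93) were left out of the clustering, the ranking of cluster genes and the gene tests. Clusters were named from fixed markers. A class was given by at least 3 of its markers among a cluster's top 10 genes by fold, with at least 3 detected in 25% of the cells. Other clusters were called CD14 monocyte-like where at least 3 of the CD14 monocyte markers were detected in 25% of cells and the top 10 genes held no more markers of another class than of this one, so most of these clusters had 0 CD14 monocyte markers among their top 10 genes. A cluster whose median RNA count was under 0.333 times that of its samples and which held no marker among its top 10 genes stayed unnamed. Scrublet called 4058 cells doublets (4.15%), including 86.0% to 93.0% of cells in 4 samples in which its threshold failed, so doublets were kept and their removal was an alternative. No cluster carried the markers of T, NK or B cells, and the tests planned for those classes were not run. CD16 monocyte-like cells, conventional dendritic-like cells and cluster 26 were compared in their place, a choice made after the clusters were seen.

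Class shares of each sample were compared between time points with a two-sided paired permutation test of 100000 sign flips, adjusted by Benjamini-Hochberg over 18 tests. For genes, raw counts were summed per sample and class with at least 10 cells and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM normalization, a filter on low counts and the donor as a block. Antibody counts were summed and tested in the same way. Changes are at an adjusted p under 0.05 by Benjamini-Hochberg, and fold changes come from this fit. The 25 gene lists were tested with camera at a preset correlation of 0.01 (limma 3.58.1) where at least 4 members were measured, and again with an estimated correlation. In CD14 monocyte-like cells the text names the 10 genes with the largest rise and the 10 with the largest fall among those past the test at an average log2 CPM of at least 4 and with the same sign in at least 75% of donor pairs. In each other class it names 5 and 5. Receptor segment, HLA, mitochondrial, ribosomal and haemoglobin genes are named only as members of a list. For antibodies it names PD-1 and the 5 and 5 with the largest changes past the test. Coordinates are those of GRCh38.p14, the assembly of the annotation table used here, and were not taken from the deposited counts.

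The steps were tested on simulated counts drawn from the real means and library sizes with 200 changed genes. In the T02 against T01 comparison edgeR recovered 49.3% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 100% of those changed 4-fold over the 11299 genes of CD14 monocyte-like cells. Over the 5040 genes of conventional dendritic-like cells it recovered 38.8%, 88.1% and 100%, over the 3166 genes of cluster 26 31.3%, 82.1% and 100%, and over the 5815 genes of CD16 monocyte-like cells 2.99%, 25.4% and 80.3%. It made 0 calls in each class where no gene was changed. Of 100 unchanged lists camera passed at most 1 at a p under 0.05, while fry passed 34 in conventional dendritic-like cells, so fry was not used. The simulated genes were drawn independently and with no donor effect. The simulation therefore does not test camera's preset correlation on lists whose genes vary together. The ribosomal protein list, for one, had an estimated correlation of 0.761 in CD14 monocyte-like cells.

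Alternatives were no donor block, DESeq2 1.42.0 for genes and limma on centred log-ratios for antibodies, no low-count filter, a stricter cell filter (at least 500 genes and at most 10% mitochondrial counts, 61029 cells), removal of doublets, at least 30 cells per sample and class, 1 run per sample, only the 15 donors with all 4 time points, Leiden resolution 1, and a centred log-ratio scale for shares. Leaving out or modelling the 18 libraries with a median of under 7500 antibody counts per cell (7, 4, 4 and 3 libraries at T01 to T04), a limit of 2000 genes per cell, thinning of every CD14 monocyte-like sum to 939056 counts and removal of doublets in all but 4 samples were added after the data were seen. Values were computed with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3 and drawn with Matplotlib 3.10.9.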

Results

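The series profiled peripheral blood mononuclear cells, the lymphocytes, monocytes and dendritic cells left after red cells and granulocytes are removed from blood. The blood came from patients with biliary tract cancer in a Phase II trial of pembrolizumab, an antibody against the immune checkpoint receptor PD-1, given with GM-CSF, a growth factor for myeloid cells. Droplet-based 3′ sequencing read both the RNA of each cell and 99 DNA-barcoded antibodies bound to its surface. The labels place the samples at 4 time points, T01 to T04, and follow the same donors across them. They give no day for a time point and do not say whether T01 came before treatment, so every change below is a change relative to T01. There were 18 samples at T01, 17 at T02, 17 at T03 and 16 at T04, from 18 donors, of whom 15 had all 4 time points. The deposited matrices held 97817 cells in 68 samples. Total RNA counts per sample ran from 1748533 to 23341500 at T01 (median 9629631), from 2374474 to 23845100 at T02 (median 6809374), from 1825190 to 18774825 at T03 (median 5908266) and from 3556615 to 21242092 at T04 (median 8045337). Median antibody counts per sample were 18479895, 13131847, 9424736 and 21559344 at T01 to T04.

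Most of the cells analysed here were myeloid. Clustering gave no cluster that carried the T cell, NK cell or B cell markers fixed in advance. Lymphocytes are a main part of blood mononuclear cells, so the deposited cells appear to be a myeloid part of them. Shares below are shares of all deposited cells, not of all blood mononuclear cells. Each deposited cell had at least 500 RNA counts and at most 2500 detected genes. Whether the choice of cells acted alike at all time points was not tested. Most cells were CD14 monocyte-like, the classical monocytes of blood. CD16 monocyte-like cells, the non-classical monocytes that carry the Fc receptor FCGR3A, made up clusters 0 and 2. Conventional dendritic-like cells, which present antigen to T cells, made up clusters 11 and 22. Cluster 26 was led by PTGDS, JCHAIN, GZMB, C12orf75 and ITM2C. Its top genes held JCHAIN and MZB1 of the fixed plasma cell markers and SERPINF1 of the plasmacytoid dendritic markers. These were too few for a name by the rule, so it was compared by its number. Its top genes also held IGKC, IRF4 and PLD4, which are in neither marker list. Whether the cluster held either of these cell types or mixed both was not tested. Cluster 23 was named platelet-like from its top genes, among them PPBP and PF4. It also had 13 detected CD14 monocyte markers, FCGR3A among its top genes and a median of 6351 RNA counts per cell. The name therefore does not mean platelets alone. Whether these cells were monocytes that carried platelet RNA was not tested. Cluster 7, with a median of 1440 RNA counts per cell, stayed unnamed.

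The first comparison asked how the makeup of the deposited cells changed over the time points. The share of CD16 monocyte-like cells fell from 8.62% ± 7.26 (SD, n = 18) at T01 to 0.843% ± 1.37 (n = 17) at T02, and was lower in 17 of 17 donors with both times. The mean paired difference was -8.18 percentage points (paired permutation test with sign flips, two-sided, p = 3e-05, adjusted p = 0.00054 over 18 tests by Benjamini-Hochberg). The share was 5.61% at T03 and 10.4% at T04, and neither difference from T01 passed the test (adjusted p = 0.364 and 0.807). Conventional dendritic-like cells fell from 6.83% to 2.28% at T02, lower in 15 of 17 donors (-4.80 percentage points, adjusted p = 0.00594). CD14 monocyte-like cells rose from 77.2% to 91.2%, higher in 15 of 17 donors (14.4 percentage points, adjusted p = 0.00171). Cluster 26 held 3.16% of cells at T01 and 1.59% at T02, a difference that did not pass the test (-1.51 percentage points, lower in 11 of 17 donors, adjusted p = 0.0563). It passed under the strict cell filter (-3.67, adjusted p = 0.0337) and with cells called doublets left out (-1.75, adjusted p = 0.00675), but not with the 4 samples of failed doublet calling spared (-1.51, adjusted p = 0.0581). At T03 and T04 no class passed the test against T01 in these 18 tests.

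**Figure D1:**
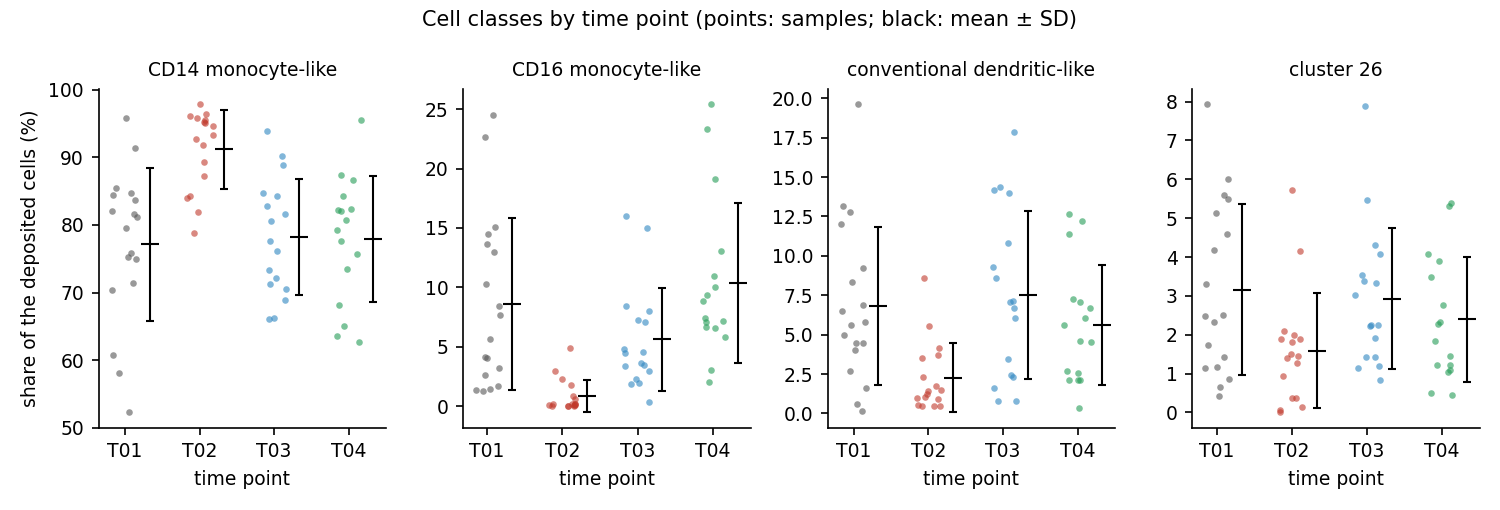
Shares of 4 cell classes among the deposited cells (%, vertical axis) at each time point (horizontal axis). Coloured points are samples and black bars the mean ± SD over 18, 17, 17 and 16 samples, with the CD16 monocyte-like share at a mean of 8.62% at T01 and 0.843% at T02.

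Antibody depth split the libraries into 18 with a median of 3078 to 5136 antibody counts per cell and 66 with 10473 to 24574. Without the 18 libraries of low antibody depth the CD16 monocyte-like difference at T02 was -8.31 percentage points. The differences of the conventional dendritic-like and CD14 monocyte-like cells became -2.20 (adjusted p = 0.297) and 9.51 (adjusted p = 0.12) percentage points and no longer passed the test. Only 2 donors had both T01 and T02 in low-depth libraries, too few for a value within that batch. With cells called doublets left out, neither of these 2 classes passed (-4.26, adjusted p = 0.0593, and 9.26, adjusted p = 0.34), but the caller's threshold had failed in 4 samples. With the cells of these 4 kept, both passed (-4.74, adjusted p = 0.006, and 14.2, adjusted p = 0.00171). On a centred log-ratio scale, which sets each class against the mean log count over the classes of a sample, the conventional dendritic-like cells did not pass (adjusted p = 0.59). The values of a sample have a fixed sum on this scale too. The fall of the CD16 monocyte-like cells therefore raises the values of the other classes.

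The second comparison asked which genes changed in the CD14 monocyte-like cells. At T02 they showed a broad change. MRC1, the macrophage mannose receptor CD206, rose from 1.4 ± 1.26 CPM (SD, n = 18) at T01 to 148 ± 125 CPM (n = 17) at T02, 96.3-fold in the paired fit (log2 fold change 6.59, standard error 0.45, adjusted p = 5.2e-17 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and was higher in 16 of 17 donors. MRC1 (ENSG00000260314) lies on chromosome 10 at 17809348 to 17911164 in GRCh38.p14. GGT5, a gamma-glutamyltransferase family enzyme on chromosome 22 at 24219654 to 24245142, rose by 5.37 ± 0.35 (log2, standard error), from 2.56 to 88.1 CPM. PMP22 rose by 2.93 and CSF1, the macrophage colony-stimulating factor, by 2.55. TNFRSF18, the costimulatory receptor GITR, rose by 2.29, SLC44A1, a choline transporter, by 2.00, CLU, the extracellular chaperone clusterin, by 1.93, EPAS1, the hypoxia-inducible factor HIF-2α, by 1.76, STEAP4, a metalloreductase, by 1.73, and ACP5, tartrate-resistant acid phosphatase, by 1.60. In all, 1266 of 11299 tested genes changed, 753 up and 513 down.

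Of the genes that fell in the CD14 monocyte-like cells at T02, FCGR1A, the high-affinity IgG receptor, fell from 37.4 to 14.2 CPM (log2 fold change -1.37 ± 0.19, standard error, lower in 16 of 17 donors). The scavenger receptors MSR1 and MARCO changed by -1.17 and -1.03, and the C-type lectin CLEC4D by -1.01. ZFP36L1, an RNA-binding protein that promotes mRNA decay, changed by -1.33, VNN2 by -1.10, CAMK2D by -1.07, and the long noncoding RNAs LUCAT1 and LINC00937 by -1.05 and -1.02. FCGR3A, the CD16 receptor and a marker of the other monocyte class, fell from 25.9 ± 54.5 CPM (SD, n = 18) to 5.88 ± 3.43 CPM (n = 17), with a log2 fold change of -1.475 ± 0.34 (standard error) in the paired fit and lower values in 15 of 17 donors (chromosome 1, 161541759 to 161550737). The trafficking receptor gene CX3CR1 fell too (-2.73), and the CD16 monocyte-like share fell in the same samples. The CD16 antibody signal in the CD14 monocyte-like cells did not follow (log2 fold change 0.015, adjusted p = 0.909, higher in 8 of 17 donors). FCGR3A shares most of its sequence with FCGR3B, so its counts are uncertain. Each of these genes passed edgeR's test at an adjusted p under 0.05.

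**Figure D2:**
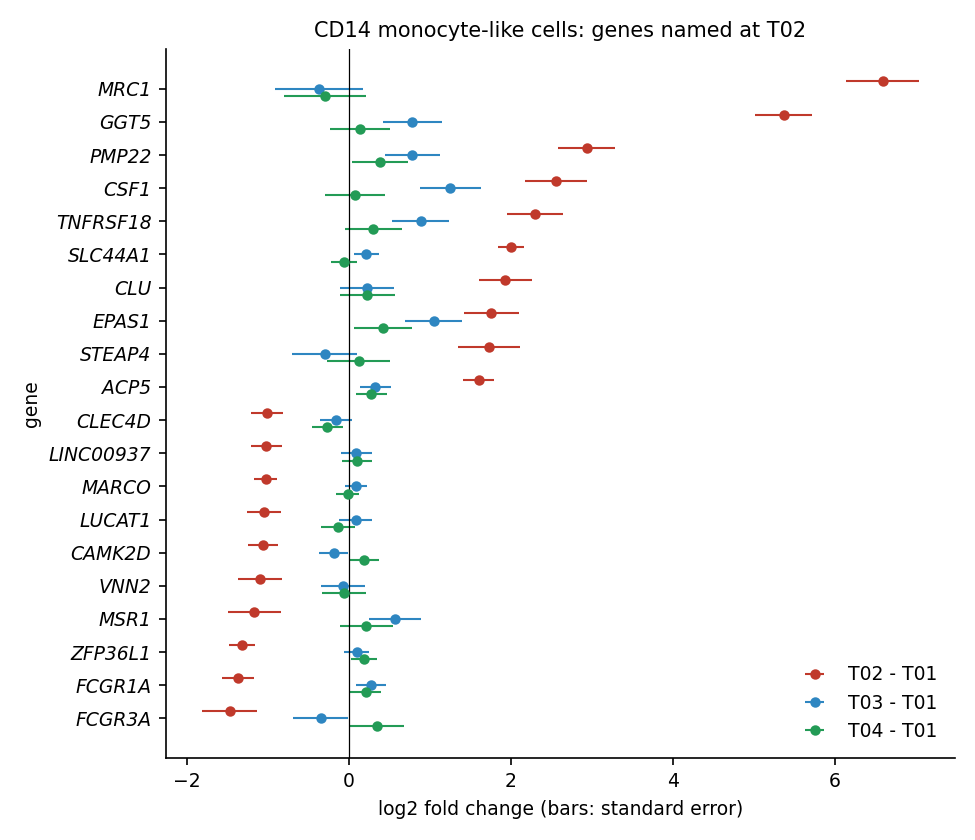
Log2 fold changes of the 20 genes named by the fixed rule in CD14 monocyte-like cells, with the gene on the vertical axis and its change at T02 (red), T03 (blue) and T04 (green) relative to T01 on the horizontal axis. Points are edgeR estimates and bars their standard errors, with MRC1 at 6.59 and FCGR1A at -1.37 at T02.

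The gene lists fixed in advance moved as follows in these cells. Of 15 measured genes of the GM-CSF receptor and STAT5 target list, 6 rose and 0 fell, and 7 rose when adjusted over the list alone. They were the receptor subunits CSF2RB (0.49) and IL3RA (1.58), the STAT5-induced feedback inhibitors CISH (1.61) and SOCS2 (3.02), the kinase PIM1 (1.10) and the interleukin-2 receptor chain IL2RA (3.74). The list rose as a set (camera, adjusted p = 2.61e-06), also with an estimated correlation (adjusted p = 0.00884). Of 11 MHC class II genes, which present antigen to CD4 T cells, 10 rose, among them HLA-DQB1 (1.16), HLA-DRA (0.70), CIITA (0.87), their master regulator, and CD74 (0.45), while the protease CTSS fell (-0.49). The counts were the same adjusted over the list alone. The set test gave an adjusted p of 5.36e-11 but missed the threshold with an estimated correlation (adjusted p = 0.0521). Of 9 costimulation and dendritic maturation genes MRC1, CD40 (1.12) and CD80 (1.11) rose, so 3 in all, with 4 up and 1 down adjusted over the list alone (camera adjusted p = 0.0022, and adjusted p = 0.0521 with an estimated correlation). Of 20 type I interferon response genes 3 rose, IFI6 (1.24), ISG15 (0.99) and IFI44 (0.81), and 3 adjusted over the list alone (camera adjusted p = 0.00482, but adjusted p = 0.661 with an estimated correlation).

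Other lists fell or split. Of 16 ribosomal protein genes 15 fell, and 16 adjusted over the list alone, each by a small amount (median -0.30). That set's camera adjusted p was 1.7e-13, and its adjusted p = 0.121 with an estimated correlation. Of 11 mitochondrially encoded genes 1 fell, MT-ND3 (-0.28), also adjusted over the list alone (camera adjusted p = 0.00861, adjusted p = 0.595 with an estimated correlation). Of 15 interferon gamma response genes 1 fell, FCGR1A, also adjusted over the list alone (camera adjusted p = 0.0459, adjusted p = 0.661 with an estimated correlation and 0.0886 without the donor block). Among 10 Fc and complement receptor genes 2 rose, the inhibitory receptor FCGR2B (1.67) and the complement subunit C1QA (1.52), and 4 fell, FCGR1A, FCGR3A, the anaphylatoxin receptors C3AR1 (-0.80) and C5AR1 (-0.28), with 3 up and 4 down adjusted over the list alone. The set did not pass (camera adjusted p = 0.504). Of 6 platelet genes 2 rose, CAVIN2 (0.59) and GNG11, and 4 adjusted over the list alone (camera adjusted p = 0.0138, adjusted p = 0.409 with an estimated correlation). The list of immediate early and heat shock genes, which respond to cell handling, did not pass (camera adjusted p = 0.104), although JUN (0.71) and JUNB (0.64) rose, 2 of its 16 genes both over all genes and adjusted over the list alone.

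**Figure D3:**
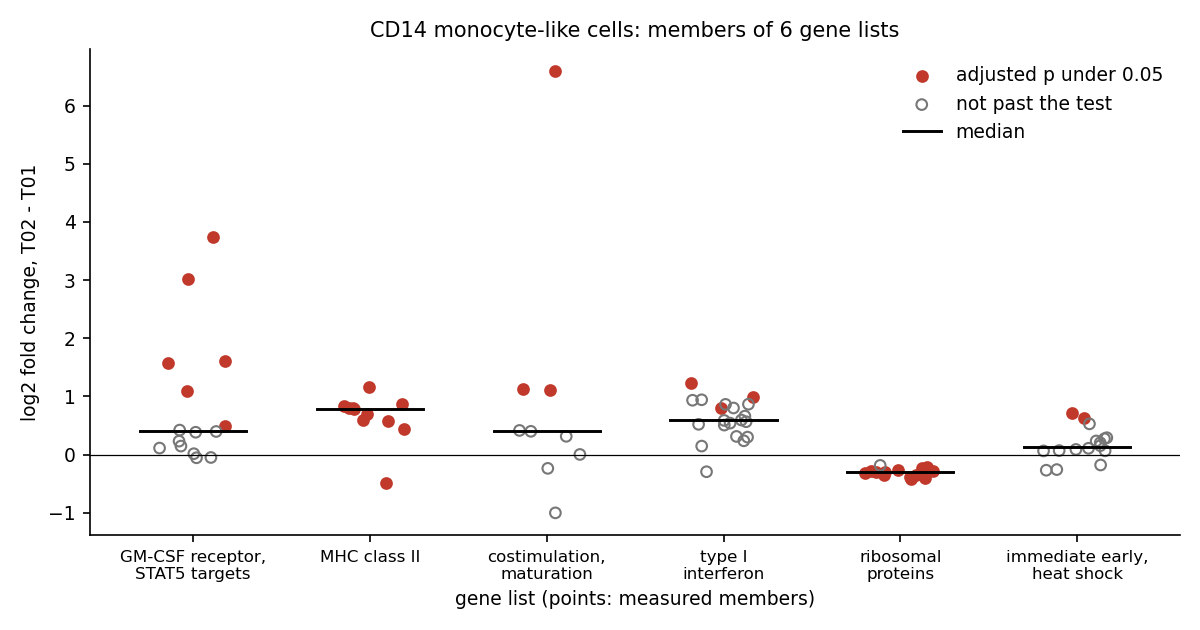
Log2 fold changes at T02 relative to T01 (vertical axis) of the measured members of 6 gene lists (horizontal axis) in CD14 monocyte-like cells. Red points passed edgeR's test at an adjusted p under 0.05, open points did not, and black bars are list medians, with 6 red points of 15 in the STAT5 target list and 11 of 11 in the MHC class II list.

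The clusters that held the largest parts of the CD14 monocyte-like cells differed between the 2 times. At T01 clusters 5 and 4 held 18.9% and 15.2% of them, and at T02 6.59% and 5.43%. At T02 clusters 28 (led by CSF1, TNFRSF18, GGT5 and PMP22) and 20 (led by MRC1, F13A1, GGT5 and STEAP4) held 15.2% and 14.4%. At T01 these 2 held 0.064% and 0.251%. The values above thus compare a class whose makeup by cluster differed strongly between the times. Without the libraries of low antibody depth the count was 615 genes (391 up, 224 down), and with that batch as a term it was 1538. Of the genes tabulated by name over all 4 cell classes, 45 lost the call without these libraries and 58 kept it, and without the donor block 36 lost it and 69 kept it.

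Surface antibodies gave 8 changes of 99 in the CD14 monocyte-like cells at T02, 7 up and 1 down. The antibody signal of PD-1, the target of pembrolizumab, did not pass the test (log2 fold change -0.16 ± 0.07, standard error, edgeR adjusted p = 0.209 at T02, adjusted p = 0.997 at T03 and 0.68 at T04). It was low, at 726 CPM of the antibody counts at T01 and 649 at T02, against 12312 for CD54 at T01. Whether so low a signal lay above background was not tested. CD206, the protein of MRC1, rose 15.2-fold, from 758 ± 171 (SD, n = 18) to 12549 ± 7670 (n = 17) CPM of the antibody counts, in 16 of 17 donors (adjusted p = 8.19e-21). CD54 (ICAM1), an adhesion molecule, rose 1.86-fold in 17 of 17 donors, the activation marker CD69 1.77-fold, CD141 (THBD), thrombomodulin, 1.68-fold, and CD123 (IL3RA), the interleukin-3 receptor, rose by 0.58 on the log2 scale. CD13 (ANPEP), an aminopeptidase, changed by -0.36 on the log2 scale. No antibody passed edgeR's test at T03 (0 changed, 1 at an unadjusted p under 0.05) or T04 (0 changed, 11 at an unadjusted p under 0.05), and limma on centred log-ratios gave 0 at both.

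**Figure D4:**
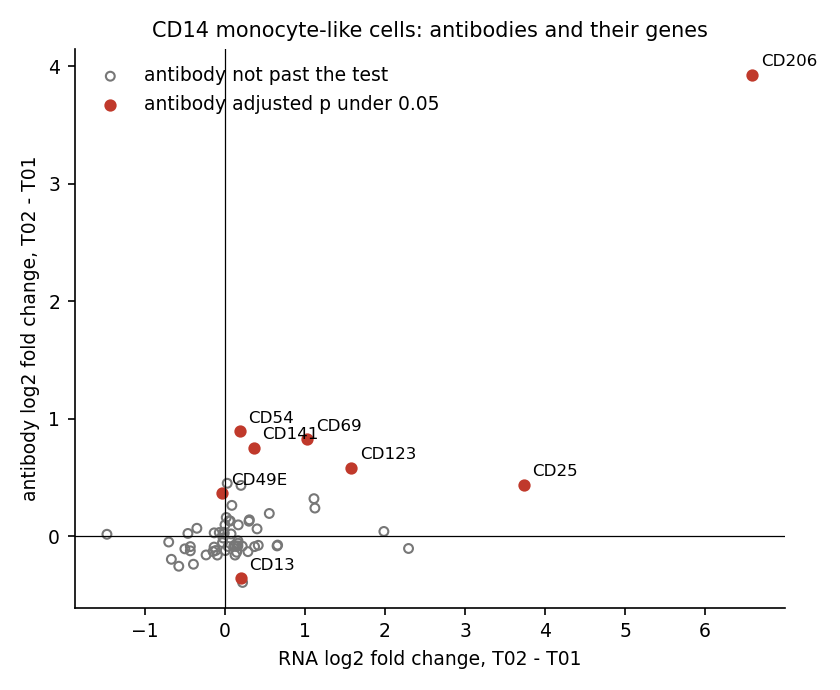
Log2 fold change of the antibody signal (vertical axis) against that of the gene's RNA (horizontal axis) at T02 relative to T01 in CD14 monocyte-like cells, 1 point for each of 63 antibodies whose gene was tested. Red points are antibodies past edgeR's test, among them CD206 (MRC1) at 3.93 for the antibody and 6.59 for the RNA.

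At T03 and T04 few genes of the CD14 monocyte-like cells passed the test against T01. At T03, 1 gene changed, PNMA1, which rose by 0.79 (adjusted p = 0.018, higher in 16 of 17 donors) and was below the expression floor of the naming rule, so that it was chosen after its values were seen. It was lost (0 genes) without the donor block and under 7 other alternatives. edgeR called 0 genes at T04, where 152 had an unadjusted p under 0.05. DESeq2 called 1 at T03 and 0 at T04. MRC1 averaged 0.913 CPM at T03 and 1.13 CPM at T04, and HLA-DQB1 326 and 364 CPM. As sets, the inflammatory cytokine, cytotoxic effector and ribosomal protein lists passed upward at T03 (camera adjusted p = 0.0306 each, adjusted p = 0.937 each with an estimated correlation). At T04 the lists of T cell and B cell markers passed upward and the mitochondrially encoded genes downward (camera adjusted p = 7.39e-04, 0.00287 and 1.17e-08, adjusted p = 0.0635, 0.0566 and 0.0956 with an estimated correlation). The interferon gamma and cytotoxic effector lists passed upward there too (camera adjusted p = 0.0061 each, adjusted p = 0.674 and 0.475 with an estimated correlation). In these lists 0 members passed edgeR's test at T03 or T04 over all genes, and adjusted over the list alone 1 cytotoxic gene rose at T03 and 2 B cell genes at T04. Between T02 and T03 1701 genes changed, 876 up and 825 down. Of the ribosomal protein genes 16 of 16 rose, also adjusted over the list alone, and of the MHC class II genes 10 of 11 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 2.45e-16 and 4.84e-11, adjusted p = 0.0664 and 0.0577 with an estimated correlation). Of the GM-CSF receptor and STAT5 target genes 6 of 15 fell, and 8 adjusted over the list alone (camera adjusted p = 2.16e-04, adjusted p = 0.0577 with an estimated correlation). The costimulation and type I interferon lists passed downward too (4 of 9 and 3 of 20 genes, 6 and 3 adjusted over the list alone, camera adjusted p = 0.00285 and 0.0105). The interferon gamma and mitochondrially encoded lists passed upward (2 of 15 and 2 of 11 genes, 4 and 2 adjusted over the list alone, camera adjusted p = 0.00384 and 0.0105). With an estimated correlation these lists had adjusted p = 0.0577, 0.793, 0.665 and 0.665. Between T03 and T04 edgeR called 0 genes, with 819 at an unadjusted p under 0.05, and DESeq2 called 0. As sets, the inflammatory cytokine, mitochondrially encoded and ribosomal protein lists passed downward between these times (camera adjusted p = 0.00413, 1.51e-04 and 1.44e-04, adjusted p = 0.602 each with an estimated correlation), with 0 members each over all genes or adjusted over the list alone.

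The third comparison looked at the conventional dendritic-like cells, with 17 samples of at least 10 cells at T01 and 14 at T02. MRC1 rose here as well, 9.75-fold from 21.2 ± 20.5 to 167 ± 110 CPM (log2 fold change 3.29 ± 0.36, standard error, edgeR adjusted p = 1.21e-08, higher in 12 of 13 donors). S100B, a calcium-binding protein, rose by 2.09, TNFRSF18 by 1.82, SLC44A1 by 1.80 and the complement gene C1QA by 1.74. PELI2, an E3 ubiquitin ligase, changed by -1.11 and was lower in 13 of 13 donors, IL1R2, the decoy receptor for interleukin-1, by -0.92, ZNF791 by -0.81, C15orf39 by -0.79 and PNN by -0.53. In all 33 of 5040 tested genes changed, 25 up and 8 down, and 16 without the donor block. Without the libraries of low antibody depth 3 changed, and among samples of at least 30 cells 0 changed. Among the lists, the costimulation list rose as a set (1 of 8 genes, MRC1, also adjusted over the list alone, camera adjusted p = 0.00264, and adjusted p = 0.0166 with an estimated correlation). The MHC class II and type I interferon lists each had 1 rising gene, HLA-DRB1 (0.35) and IFITM3 (1.34), or 4 of 11 and 7 of 12 adjusted over the list alone, with camera adjusted p = 9.65e-06 for both and adjusted p = 0.197 for both with an estimated correlation. The ribosomal protein list passed downward (0 of 16 genes, 13 adjusted over the list alone, camera adjusted p = 1.55e-04), as did the immediate early and heat shock list (0 of 14 genes, 0 adjusted over the list alone, camera adjusted p = 0.0459), and the interferon gamma list upward (0 of 9 genes, 2 adjusted over the list alone, camera adjusted p = 0.0331). For these 3 lists adjusted p = 0.468 with an estimated correlation, and without the donor block it was 0.0767, 0.0767 and 0.0883. Of 99 antibodies 6 rose and 0 fell, led by CD206 (3.80, log2), the costimulatory ligand CD80 (1.57), CD54 (0.77), CD69 (0.69) and CD11b (0.62). Among samples of at least 30 cells 1 of the 6, CD206, passed. PD-1, low here too at 711 and 836 CPM of the antibody counts at T01 and T02, differed by 0.10 ± 0.15 (standard error), which did not pass (edgeR adjusted p = 0.792). edgeR called 0 genes at T03 and at T04, with 625 and 161 at an unadjusted p under 0.05, and DESeq2 called 12 and 0. At T03 edgeR called 38 genes without the libraries of low antibody depth and 160 with no low-count filter, which gave 7 at T04. As sets, the MHC class II and mitochondrially encoded lists passed downward at T04 (each 0 of 11 genes, 4 adjusted over the list alone, camera adjusted p = 3.43e-08 and 8.11e-07, adjusted p = 0.138 for both with an estimated correlation) and the inflammatory cytokine list upward (0 of 12 genes, 0 adjusted over the list alone, camera adjusted p = 0.00434, adjusted p = 0.374 with an estimated correlation). Over all samples clusters 11 and 22 held 896 and 659 of the dendritic-like cells at T01 but 858 and 80 at T03, so the makeup of the class differed. At T03 the glucocorticoid response and the immediate early and heat shock lists passed downward (camera adjusted p = 0.0314 for both), with 0 genes each and 2 and 0 adjusted over the list alone. For both, adjusted p = 0.711 with an estimated correlation, and without the donor block it was 0.0592 and 0.0601.

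The last comparison concerned the 2 smaller populations. Only 5 samples at T02 had at least 10 CD16 monocyte-like cells, which limits what could be detected. In them 10 of 5815 genes changed, 8 up and 2 down. They included SCGB3A1, a secretoglobin (3.32 ± 0.46, log2 and standard error, edgeR adjusted p = 2.8e-05), PMP22 (2.43), TMEM176A (2.35), ACP5 (1.82) and CD74 (1.05), and the kinase LYN (-0.65) and IGBP1 (-1.31). The MHC class II list rose, 3 of 11 genes and 10 adjusted over the list alone (camera adjusted p = 5.78e-17, and adjusted p = 0.00789 with an estimated correlation). In the same samples the immediate early and heat shock list, which responds to cell handling, rose as a set (median 0.44, 0 of 16 genes and 2 adjusted over the list alone, camera adjusted p = 0.00211, adjusted p = 0.30 with an estimated correlation). In cluster 26, 4 of 3166 genes changed over 9 donors with both times, all 4 up, LTB, encoding lymphotoxin beta (1.96 ± 0.30), CD52 (1.16), JCHAIN (0.91) and CHCHD2 (0.46). The MHC class II list passed downward there (median -0.25, 0 of 11 genes, 0 adjusted over the list alone, camera adjusted p = 0.00814, adjusted p = 0.943 with an estimated correlation and 0.214 without the donor block). Without the donor block the counts of genes in the CD16 monocyte-like cells and cluster 26 were 1 and 2. Under the strict cell filter 0 genes passed in the CD16 monocyte-like cells, and among samples of at least 30 cells 0 passed in cluster 26. In donors with all 4 time points 1 gene passed in each, and without the libraries of low antibody depth 1 in cluster 26. At T03 and T04 edgeR called 0 genes in both populations, with 341 and 160 at an unadjusted p under 0.05 in the CD16 monocyte-like cells and 307 and 80 in cluster 26, and DESeq2 called 1 and 0 in the CD16 monocyte-like cells and 0 and 0 in cluster 26. As sets, in the CD16 monocyte-like cells the inflammatory cytokine list passed upward at T03 (camera adjusted p = 1.18e-04, adjusted p = 0.968 with an estimated correlation). Over all samples clusters 0 and 2 held 684 and 2100 of these cells at T01, 51 and 91 at T02, and 530 and 472 at T03. The makeup of the class therefore differed at T03 and, to a lesser extent, at T02, which also limits the T02 values above. At T04 the mitochondrially encoded and ribosomal protein lists passed downward and the alarmin list upward (camera adjusted p = 4.18e-07, 9.89e-07 and 0.0215, adjusted p = 0.403, 0.409 and 0.409 with an estimated correlation), the last not without the donor block (adjusted p = 0.0948). In these lists 0 genes passed, over all genes or adjusted over the list alone.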

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

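The comparison of gene list changes between cell classes used lists fixed in advance, and the repeat at matched depth was chosen after the result was seen. For each of 8 lists, the mean log2 change at T02 over the members measured in both classes was taken per donor in CD14 monocyte-like and in conventional dendritic-like cells, and the difference was tested over 13 donors (two-sided permutation test with sign flips, Benjamini-Hochberg over 8 lists). The changes differed between the classes for 4 lists. The GM-CSF receptor and STAT5 target list changed by 0.505 in the CD14 monocyte-like and by -0.107 in the conventional dendritic-like cells, as means of log2 CPM differences within donors, a difference of 0.611 (SD 0.375, higher in 12 of 13 donors, adjusted p = 0.00392). With the CD14 monocyte-like sums thinned to the total of the dendritic-like sums the difference was 0.529 (adjusted p = 0.00272). In edgeR's fit over all samples the 8 members measured in the dendritic-like cells had a mean of 0.103 and did not pass as a set (camera adjusted p = 0.507), so the sign in that class depended on the calculation. The MHC class II list differed by 0.415 (10 of 13 donors, adjusted p = 0.0143), and by 0.378 at matched depth, which no longer passed (adjusted p = 0.0516). The costimulation list differed by 0.364 (10 of 13 donors, adjusted p = 0.0143) and the Fc and complement receptor list by 0.357 (11 of 13 donors, adjusted p = 0.0235). At matched depth these 2 differences were -0.184 and -0.0813 (adjusted p = 0.215 and 0.862), so they depended on the deeper counts of the CD14 monocyte-like cells. No biological explanation was tested for these differences.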

How the results depend on the processing

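The alternatives that concern libraries of low antibody depth, the limit of 2000 genes, thinning and the 4 samples of failed doublet calling were chosen after the data were seen, and the others were fixed before the data were examined. The fall of the CD16 monocyte-like share at T02 kept its direction and passed the test under all 10 alternatives run for it, at -7.46 to -9.05 percentage points and -3.18 on the centred log-ratio scale. Over results and settings, 159 of the share results were the same, as were 991 of the named genes (223 lost the call with the same direction), 108 of the named antibodies (8 lost the call), 113 of the gene counts and 40 of the antibody counts. Of the adjusted p-values of single lists, 38 stayed on the same side and 50 lost the call. Low counts limited the CD16 monocyte-like cells most, with 5 samples of enough cells at T02 and 25.4% of simulated 2-fold changes recovered, against 82.1% to 88.1% in the other 3 classes. Where no cause is named below, the cause was not tested.

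Without the donor block (no pairing), the count of changed genes was 0 for CD14 monocyte-like cells at T03, 1 for CD16 monocyte-like cells at T02, 2 for cluster 26 at T02 and 16 for conventional dendritic-like cells at T02, and 1 antibody passed in the latter at T04. The unpaired counts of lists past the test were 4 for CD16 monocyte-like and 3 for conventional dendritic-like cells at T02, 0 for the latter at T03, and 0 and 2 for cluster 26 at T02 and T04. With an estimated correlation in place of the preset one, 1 list each passed at T02 in CD14 monocyte-like, CD16 monocyte-like and conventional dendritic-like cells. In that setting 0 passed in these 3 classes at T03 and T04, between T02 and T03 and between T03 and T04 in CD14 monocyte-like cells, and in cluster 26 at T02.

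DESeq2 gave 23 and 1 genes for CD16 monocyte-like cells at T02 and T03, 11 for cluster 26 at T02, and 62 and 12 for conventional dendritic-like cells at T02 and T03. With no low-count filter, which tests more genes of few counts, the counts were 46 and 49 for CD16 monocyte-like cells at T02 and T03, 15, 36 and 1 for cluster 26 at T02 to T04, 164, 160 and 7 for conventional dendritic-like cells at T02 to T04, and 0 for CD14 monocyte-like cells at T03. With at least 30 cells per sample, which leaves fewer samples, they were 4, 0 and 0 at T02 for CD16 monocyte-like cells, cluster 26 and conventional dendritic-like cells, with 1 antibody and a PD-1 change of -0.23 in the last.

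The strict cell filter gave 0 genes for CD14 monocyte-like cells at T03, 0 for CD16 monocyte-like cells at T02, and 11 and 1 for conventional dendritic-like cells at T02 and T03, a fall of cluster 26 of -3.67 percentage points at T02 that passed (adjusted p = 0.0337) and -0.137 for unnamed cells at T02. Without doublets, the shares at T02 moved by 9.26 for CD14 monocyte-like (adjusted p = 0.34), -4.26 for conventional dendritic-like (adjusted p = 0.0593) and -1.75 for cluster 26 (adjusted p = 0.00675), and by -1.62 for CD14 monocyte-like cells at T03. Genes changed were 0 for CD14 monocyte-like cells at T03 and 18 for conventional dendritic-like cells at T02. With the 4 samples of failed calling spared, the CD14 monocyte-like and conventional dendritic-like shares passed at T02 (14.2 and -4.74, adjusted p = 0.00171 and 0.006), and the CD14 monocyte-like share moved by -0.0454 at T03. On the centred log-ratio scale the values were -0.175 and -0.101 for CD14 monocyte-like cells at T03 and T04, -0.368 for conventional dendritic-like (adjusted p = 0.59) and 0.498 for platelet-like cells at T02, and 0.445 for unnamed cells at T04, where Leiden resolution 1 gave 0.551 percentage points. Among cells of at most 2000 genes the CD16 monocyte-like share moved by -0.963 at T04.

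With 1 run per sample, which leaves fewer cells, 0 genes changed in CD14 monocyte-like cells at T03 and 14 in conventional dendritic-like cells at T02. In donors with all 4 time points, which are fewer, 0 genes changed in CD14 monocyte-like cells at T03, 1 in CD16 monocyte-like cells and 1 in cluster 26 at T02, and the CD14 monocyte-like share moved by -0.366 at T03. Thinned to equal totals, which leaves fewer counts, CD14 monocyte-like cells gave 113 genes at T02, 0 at T03 and 192 between T02 and T03. Of the 998 genes called at T02 and still tested, 955 kept their sign (95.7%), with a slope of 0.965 on the unthinned log2 changes. The platelet gene GNG11 then stood at -0.075 and PCNA, a cell cycle gene that fell by 0.43, at 0.23 at T02, both without a call.

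Without libraries of low antibody depth, which leaves fewer samples, the shares moved by 9.51 for CD14 monocyte-like (adjusted p = 0.12) and -2.20 for conventional dendritic-like cells at T02 (adjusted p = 0.297), -3.53 and -4.80 for CD14 monocyte-like cells at T03 and T04, 0.618 for cluster 26 at T03 and -0.0843 for platelet-like cells at T04. Genes changed were 615, 0 and 853 in CD14 monocyte-like cells at T02, at T03 and between them, 1 in CD16 monocyte-like cells at T03, 1 and 1 in cluster 26 at T02 and T03, and 3 and 38 in conventional dendritic-like cells at T02 and T03. PD-1 in the last stood at -0.055 at T02 and 0.015 at T04. With the batch as a term the counts were 4 for CD16 monocyte-like cells at T03 and 57 and 1 for conventional dendritic-like cells at T02 and T03.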

Other observations

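The classes compared, the tests on libraries of low antibody depth, the depth test that uses T03 and the comparison of RNA with antibodies were chosen after results were seen. Across the 63 antibodies whose gene was tested in CD14 monocyte-like cells, the log2 changes at T02 of antibody and RNA correlated at r = 0.764 (permutation p = 0.00021) and rho = 0.395 (permutation p = 0.00134). This is a correlation across genes, which are not independent replicates, and it rested in part on MRC1 and IL2RA, since without these 2 r was 0.304 (p = 0.0194) and rho 0.338 (p = 0.00801). In some pairs only 1 of the 2 measures passed, and the difference between them was not tested. The RNA of TNFRSF18 and TNFRSF4, costimulatory receptors, rose by 2.29 and 1.99, with antibody values of -0.11 (CD357) and 0.04 (CD134) that did not pass. The antibodies CD54, CD141 and CD49e rose by 0.89, 0.75 and 0.37, with RNA values of 0.18 for ICAM1, 0.37 for THBD and -0.03 for ITGA5 that did not pass. FCGR3A RNA fell by 1.475, with an antibody value of 0.015 (CD16) that did not pass.

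Other lists fixed in advance held few changed genes in CD14 monocyte-like cells at T02, and none of those named here passed as a set. Of 9 trafficking receptor genes CX3CR1 (-2.73) and the integrin ITGA4 (-0.70) fell, also adjusted over the list alone (camera adjusted p = 0.251). Of 10 alarmin and suppressive monocyte genes CLU rose, and the scavenger receptor CD163 (-0.67) and IL1R2 (-0.93) fell, with 1 up and 4 down adjusted over the list alone (camera adjusted p = 0.434). Of 8 checkpoint and activation receptor genes TNFRSF4 and CD69 (1.03) rose, with 3 up and 1 down adjusted over the list alone (camera adjusted p = 0.181). Of 14 inflammatory cytokine genes 0 passed edgeR's test, over all genes or adjusted over the list alone (camera adjusted p = 0.0686).

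The fall of the CD16 monocyte-like share at T02 was weighed against 3 technical explanations. Among cells of at most 2000 genes the difference was -8.44 percentage points, against -8.18 (standard error 1.58) with the deposited limit of 2500 genes, and without libraries of low antibody depth it was -8.31, which argues against both as the whole cause. CD16 monocytes placed in other clusters at T02 stay open. Summed over all cells, the 12 CD16 monocyte markers had a median log2 change of -0.557, between the bounds set for either outcome, with FCGR3A at -2.39 and LYPD2 at -2.62 (each lower in 17 of 17 donors) but HES4 at 0.341 and TCF7L2 at 0.204. The CD16 antibody over all cells changed by -0.521 (log2) and was lower in 13 of 17 donors, a smaller fall than that of FCGR3A RNA. Only shares were measured, not cell numbers. A loss of these cells from blood, a loss of their marker expression and a rise in the number of other cells may each contribute, and cannot be told apart here.

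The gene changes of CD14 monocyte-like cells at T02 were weighed against depth, batch and handling. With every sample thinned to the lowest total, 113 genes passed, under the bound set for a depth effect, but thinning costs power in every sample and the count alone does not decide. The changes stayed about as large (955 of 998 genes kept their sign, slope 0.965). Random thinning keeps ratios on average, so these values could hardly have differed and do not decide either. T03, with a larger gap in depth to T01, had 1 changed gene, which argues against depth as the whole cause. With the batch of low antibody depth as a term 1538 genes passed. Handling stays open, since the immediate early and heat shock list had a median of 0.131 and did not pass (camera adjusted p = 0.104), while its members JUN and JUNB rose, which the bound set beforehand did not provide for. A response to the treatment, as a hypothesis, may account for the rest, but the labels do not say where T02 lies relative to a dose and there is no untreated arm.

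The gene changes of conventional dendritic-like cells at T02 were weighed against RNA and cells of another type. The 25 genes that rose did so by a median of 1.43 times their rise in CPM in CD14 monocyte-like cells, above the limit of 0.0204 that free RNA would allow, judged by the share of monocyte markers in cluster 26 (0.0068). The dendritic markers of the class had a median log2 change of 0.372 (-0.502 to 1.275 over 7 markers), where monocytes counted in the class would lower it. The CD14 monocyte list, which such cells would raise, had a median of 0.31 there (0 of 11 genes, camera adjusted p = 0.0908). Genes picked for their rise would hardly lie under so low a limit, so the argument against free RNA as the whole cause rests on the low share in cluster 26. Several of the dendritic markers gave clusters 11 and 22 their name, so cells placed in the class tend to hold them. The marker value therefore does not decide, and monocytes counted in the class stay open. A change in the dendritic-like cells may remain as a hypothesis.

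Time labels were also swapped within donors. For genes in CD14 monocyte-like cells, only the real one of the 22 splits gave as many as the 1266 at T02 (highest other 69). The same held for the 1701 between T02 and T03 (highest other 579). A share of 1 of the 22 is the smallest that 22 splits can give, and it was not adjusted over the comparisons made. Both counts lay above every other split tried, but this share alone does not exclude chance. For the 1 gene at T03, 1 of the 22 splits gave as many (highest other 0), and 8 alternatives lost that call. At T02 the 33 genes of conventional dendritic-like cells (1 of the 22 splits, highest other 9) also lay above every other split. So did the 4 genes of cluster 26 (1 of the 22, highest other 1), with the same limit and only for the settings of the report. With at least 30 cells per sample both counts were 0, and without the libraries of low antibody depth they were 3 and 1. The 10 genes of CD16 monocyte-like cells at T02 had 1 of the 16 splits as large (highest other 0), and 16 splits are too few for a share under 0.05. Counts of 0 were reached by 22 of the 22 splits, with highest others of 1 and 0 for CD14 monocyte-like cells at T04 against T01 and T03, 0 and 0 for CD16 monocyte-like, 8 and 6 for conventional dendritic-like cells and 6 and 0 for cluster 26 at T03 and T04. For antibodies, 4 of the 100 splits gave as many as the 8 in CD14 monocyte-like cells at T02 (highest other 14). In conventional dendritic-like cells 2 of the 100 gave as many as the 6 (highest other 6). These shares lay under 5% but were not adjusted over the comparisons made. Other splits also reached the real counts, so chance was not excluded for the antibody counts. The antibody counts of 0 were reached by 100 of the 100 splits, with highest others of 20 and 2 at T03 and T04 in CD14 monocyte-like and 4 and 1 in conventional dendritic-like cells. The split with 20 antibodies points to a structure of the samples, whose source was not tested.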
